A study of Mus musculus with 6 samples.

How the data were processed

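RNA sequencing measured transcript levels in 6 libraries of mouse neutrophils. The cells were CD101+ Ly6G+ mature neutrophils sorted from bone marrow and cultured outside the animal, 3 libraries with DKK1 (Dickkopf-1, a secreted antagonist of Wnt signalling) and 3 without it, here called control. Per the labels' protocols, total RNA was extracted with TRIzol or a column kit and libraries were sequenced on Illumina instruments. The dose of DKK1, the length of culture and the strandedness of the libraries are not given in the sources used here.

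The deposited values are normalized counts per gene and library, per the file headers, a signal that is never negative. Reads were assigned to the mm10 build, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the way the authors set the normalization factors are not given in the sources used here. Of the gene identifiers in the deposited table, 35 matched GENCODE release M21 with their version and 51948 (91.3%) matched it without the version, so the counting annotation was another release. The table holds 56884 genes. A further 3 columns of per-sample values match no sample of the series and were not used here; the authors' factors may have been set with those columns included.

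Every value in the 6 libraries was a whole multiple of what 1 read was worth in that library (100% of values within a tolerance of 0.001 reads), so the reads behind each value could be recovered. Recovered totals were 8901520, 8688911 and 9851961 reads in control libraries 1 to 3 and 8749228, 5188116 and 8044847 in DKK1 libraries 1 to 3. Reads carry no molecular identifiers, so counting intervals and floors cover counting error alone. A floor of 3 reads over the 3 libraries of a group corresponds to a mean normalized count of 1.06 in control and 0.911 in DKK1.

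Groups were taken from sample titles, and the single contrast was DKK1 minus control. The design foresaw edgeR for raw counts and limma for normalized values. Because the values are normalized, the test was limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes) on log2(normalized count + 1). Genes with a normalized count of at least 1 in at least 3 of the 6 libraries entered, 16265 in all. P-values were two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. Folds are ratios of recovered reads pooled over the 3 libraries of each group, set to the groups' mean values of 1 read. A fold against a group at 0 reads was computed against the floor and is written "at least". With 1 to 3 reads in a group the fold has its 95% exact counting interval.

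The 30 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule took 7 genes in every case (Chil3, Cd101, Ly6g, Ckap4, Lrp5, Lrp6, Kremen1). It also took the 10 largest rises and the 10 largest falls among genes past the threshold with non-overlapping groups and a higher-group mean at or above the median, without unnamed gene models. From each list it took up to 4 members of smallest adjusted p. Any other gene named below was chosen after its values were seen. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists. Beside it stand camera with an estimated correlation, and fry, which tests whether a list's genes move on balance in a direction and does not compare them with other genes. List members were also counted singly, over all genes tested and adjusted over the list alone.

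The first set of alternatives held the replicate block, pseudocounts of 0.1 and 10, no filter, a filter of 10 in 3 libraries, median-of-ratios and quantile scaling, limma without trend or robust fitting, array weights, a log2 change of at least 1, and leaving out each library in turn. Alternatives added after seeing the data were scaling to equal total reads, removal of a GC content and transcript length trend, and tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. The GC and length values came from GENCODE M21 and covered 96.5% of tested genes.

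The limma script was tested on simulated data with 14929 genes entering and the spread of these libraries. For the simulated DKK1 minus control contrast it called 31.8% of 66 genes changed by 0.5 on the log2 scale, 55.2% of 67 changed by 1 and 91.0% of 67 changed by 2, each in the right direction. Of its calls 9.85% were false, and it made 0 calls when no change was simulated. A simulated raised list had an adjusted p of 3.28e-36 by camera, and 0 of 20 unchanged lists were called. In that list simulation genes varied independently and none outside the raised list changed. It therefore cannot tell how camera behaves with correlated members or with many changed genes, as in these data.

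Pairs of libraries within each group differed beyond counting noise (chi-square test on recovered reads), so no 2 of them were taken as copies of one library. This does not show that they came from separate cultures. Genes with near-identical copies are uncertain where reads could be shared, among them Saa3, Fth1, Ftl1, Prdx1, the H2 genes, the stefins, the globins and ribosomal protein genes. Antisense and overlapping genes could not be told apart without the strand setting of the counting.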

Results

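Transcript levels were measured by RNA sequencing in mature neutrophils sorted from mouse bone marrow as CD101+ Ly6G+ cells and cultured ex vivo, with DKK1 in 3 libraries and without it in 3, per the labels. DKK1 is a secreted protein that binds the Wnt co-receptors LRP5 and LRP6, and CKAP4 is a further receptor for it. The series concerns immature neutrophils marked by Chil3, and this contrast asks how DKK1 alters transcripts of mature neutrophils. Recovered read totals ranged from 5188116 in DKK1 library 2 to 9851961 in control library 3, and 15610 to 16751 genes were detected per library. Summed normalized counts were 9729307 ± 39771 in control and 6738824 ± 336773 in DKK1 (SD, n = 3 each). Nothing in the labels says that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

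The transcripts that define the sorted population were far lower with DKK1. Cd101, the sorting marker of mature neutrophils, fell from a normalized count of 5098 ± 178 in control to 3.53 ± 2.31 with DKK1 (SD, n = 3 each), which is 1293-fold lower. Ly6g, the other sorting marker, fell from 1338 ± 72.7 to 5.96 ± 1.30, or 232-fold. Most listed transcripts of inflammatory genes under NF-kappaB, ribosomal proteins, respiratory chain subunits and cholesterol synthesis were higher, and most interferon-induced transcripts were lower. With an estimated correlation the 4 rising lists lost their camera calls (adjusted p = 0.613, 0.269, 0.434 and 0.435 in that order) and the interferon list kept its call (adjusted p = 0.0427). Of 16265 genes tested, limma with Benjamini-Hochberg adjustment called 5709 higher and 5873 lower, and 4683 did not pass. With libraries scaled to equal total reads the split was 7098 higher and 4742 lower, 59.9% higher against 49.3%, and the median of all tested genes moved by 0.47 on the log2 scale.

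Chil3, which encodes the chitinase-like protein Ym1 and names the immature state in the series title, fell from 979.6 ± 28.0 to 58.1 ± 56.1 (16.1-fold lower, log2 change -4.48, SE 0.57, limma adjusted p = 0.000165). Its DKK1 libraries stood at 20.1, 31.6 and 122, and without DKK1 library 3 the log2 change was -5.22. Positions here and below are those of GENCODE M21 on the GRCm38 assembly (mm10), matched to the deposited identifiers without their version. Chil3 (ENSMUSG00000040809.11) lies on chromosome 3 from 106147554 to 106167564, minus strand, a protein-coding gene whose longest transcript has 11 exons. Cd101 (ENSMUSG00000086564.10) lies on the same strand of chromosome 3 from 100993529 to 101029556. Ly6g (ENSMUSG00000022582.5) lies on chromosome 15 from 75155240 to 75159126, plus strand.

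The list of DKK1 receptors and Wnt co-receptors also holds genes of the Wnt pathway inside the cell. Of its 16 tested members, 8 were higher, 4 lower and 4 did not pass. The receptor genes among those higher were Lrp6, Lrp1 and Fzd5, and the others were Ctnnb1, Axin1, Dvl1, Dvl2 and Dvl3. Those lower were Ckap4, Lrp5, Fzd4 and, inside the cell, Gsk3b. Ckap4 (ENSMUSG00000046841.6, chromosome 10, 84526305 to 84534062) fell from 2125 ± 41.7 to 46.9 ± 14.1, 43.0-fold. Lrp6 (ENSMUSG00000030201.16, chromosome 6, 134446476 to 134566965) rose 1.81-fold, from 52.2 ± 1.75 to 90.5 ± 19.6 (log2 change 0.76, SE 0.21, limma adjusted p = 0.00861). Lrp5 (ENSMUSG00000024913.17, chromosome 19, 3584828 to 3686564) fell from 24.1 ± 9.62 to 4.01 ± 5.13 (log2 change -2.87, SE 0.79, limma adjusted p = 0.00958). With a pseudocount of 0.1 its adjusted p was 0.0565, within a range of 0.0014 to 0.0565 over the alternatives. The log2 change of Lrp5 was -2.02 without DKK1 library 2 and -3.73 without DKK1 library 3. Kremen1 (ENSMUSG00000020393.17, chromosome 11, 5191552 to 5261558), a DKK receptor gene, stood at 47.1 ± 7.94 and 33.0 ± 5.02 and did not pass (limma adjusted p = 0.0921). Lrp1, an endocytic receptor gene, rose from 78.3 ± 2.37 to 1624 ± 122. The median log2 change of the list was 0.37, or 0.05 without control library 1 and 0.89 with equal total reads, its mean was -0.01, and camera did not call it (adjusted p = 0.634). Of 30 canonical Wnt target genes 15 could be tested, of which 3 were higher, 6 lower and 6 not past the threshold (camera adjusted p = 0.634). Only 4 of the 15 had a control mean of at least 100. The targets Axin2, Nkd1 and Sp5 had 0 reads in both groups, so a change in them could not be seen. Cyclin D2 (Ccnd2) fell from 579.7 ± 13.4 to 31.4 ± 21.6, and Id2 rose from 788 ± 20.4 to 1682 ± 126.

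**Figure D1:**
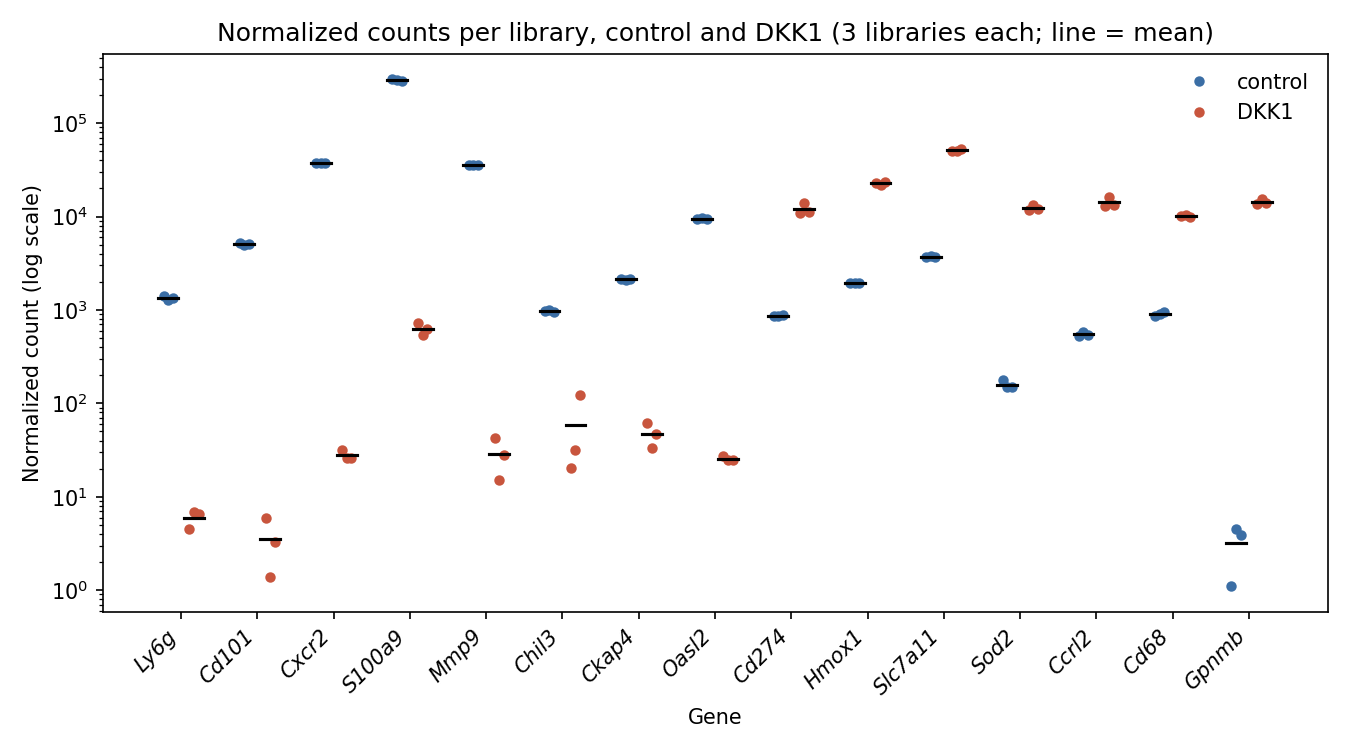
Normalized counts of 15 genes in each of the 3 control (blue) and 3 DKK1 (red) libraries on a log axis, with the group mean as a black line. Ly6g fell from a mean of 1338 to 5.96 and Gpnmb rose from 3.17 to 14292, and for each gene drawn the groups do not overlap.

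In each of the 30 lists, the numbers of members called higher and lower when adjusted over the list alone equalled those over all genes tested. Of 30 mature neutrophil genes, 27 fell and 3 rose (median log2 change -5.72, camera adjusted p = 1.37e-07), and the call held with an estimated correlation (adjusted p = 0.0427). Cxcr2, the chemokine receptor through which neutrophils leave the marrow, fell from 37246 ± 80.9 to 27.8 ± 3.00. Csf3r, the G-CSF receptor, fell from 64496 ± 854 to 652 ± 43.5. The 3 that rose were the C-type lectin receptor genes Clec4d and Clec4e and the protease inhibitor gene Slpi. The last rose from 6575 ± 50.7 to 19252 ± 1033.

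Genes of specific granules and immature neutrophils fell as well: 17 of 19 were lower, 1 was higher and 1 did not pass (median log2 change -4.74, camera adjusted p = 1.6e-05). This call was lost with an adjusted p = 0.0605 with an estimated correlation. Mmp8, neutrophil collagenase, fell 250.1-fold from 27332 ± 416 to 108 ± 6.35, and Anxa1 fell 154-fold from 8953 ± 125 to 56.3 ± 10.3. Lyz2, lysozyme, fell 4.79-fold. Orm1, an acute phase protein gene, was the member that rose, from 5.27 ± 3.64 to 853 ± 38.6. Camp (cathelicidin) did not pass. Of 16 azurophil granule and progenitor genes, 7 fell, 2 rose and 7 did not pass (median -0.90, -1.05 with groups at 0 reads placed at the floor or -0.41 with equal total reads; camera adjusted p = 0.166). Only 3 of the 16 had a control mean of at least 100, and the granule genes Mpo and Elane stood at 79.1 and 20.4 in control. Histidine decarboxylase (Hdc), far more abundant in control than these, fell 295-fold from 14339 ± 269 to 44.3 ± 24.2. Kit, the stem cell factor receptor gene, rose 7.37-fold from 32.9 ± 4.73 to 251 ± 58.2.

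The largest rises by the fixed rule were in Gpnmb, Saa3, Zc3h12c, Plxna1, Tm4sf19, Slc11a2, Il10, Met, Procr and Bhlhe41. Gpnmb, a glycoprotein gene of lysosome-rich phagocytes, rose from 3.17 ± 1.81 to 14292 ± 1096 (log2 change 11.86, SE 0.32, limma adjusted p = 2.33e-09). Slc11a2, an iron transporter, rose from 4.63 ± 1.72 to 4845 ± 313. Il10, an anti-inflammatory cytokine, had 1 read in the control libraries and 3595 in DKK1, a ratio of 3078 with a 95% counting interval of 552 to 121616. Procr, the protein C receptor, had 0 control reads and was at least 805-fold higher. The largest falls included Nlrp12, Amer2, Ipcef1, Rab11fip4, Mmp9, Cxcr2, Cd101, Jaml and Bmx. Nlrp12, an intracellular sensor of myeloid cells, fell from 5029 ± 27.2 to 1.04 ± 0.905 (log2 change -11.39, SE 0.34, limma adjusted p = 3.62e-09). Mmp9, gelatinase B, fell from 35374 ± 157 to 28.5 ± 13.7. S100a9, the most abundant control transcript, fell 444-fold from 287287 ± 6877 to 628 ± 95.

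Of 36 inflammatory genes under NF-kappaB, 26 rose, 6 fell and 4 did not pass (median log2 change 3.14, or 3.19 with groups at 0 placed at the floor; camera adjusted p = 2.81e-05). The adjusted p = 0.613 with an estimated correlation. The chemokine gene Ccl4 rose 41.6-fold from 154 ± 13.1 to 6701 ± 1469.5. The mitochondrial superoxide dismutase gene Sod2 rose 77.0-fold from 158 ± 16.9 to 12344 ± 824, and the chemerin-binding receptor gene Ccrl2 rose 25.4-fold. The members that fell included Il1b, from 22489 in control to 554 in DKK1. DKK1 library 2 lay above the mean of DKK1 libraries 1 and 3 for 30 of 32 of these genes with a DKK1 mean of at least 100. Without that library 26 genes of the list were higher and 7 lower. With all 6 libraries scaled to equal total reads 30 were higher and 4 lower.

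Type I interferon response genes moved the other way: 29 of 33 fell, 2 rose and 2 did not pass (median log2 change -4.98, camera adjusted p = 4.24e-09). The call held with an adjusted p = 0.0427 with an estimated correlation. Oasl2, an oligoadenylate synthetase-like gene, fell 369-fold, from 9510.1 ± 78.3 to 25.6 ± 1.72. Slfn5 fell from 4621 ± 32.3 to 20.4 ± 1.71, and Rigi, a cytosolic RNA sensor, from 2331 ± 25.6 to 69.9 ± 4.99. The members that rose were Bst2 and Cxcl10. Among 21 genes of MHC and antigen presentation, 10 fell, 6 rose and 5 did not pass (camera adjusted p = 0.421). The peptide transporter gene Tap1 fell 42.5-fold from 1303 ± 45.1 to 29.9 ± 5.79. H2-D1, an MHC class I heavy chain with near-identical copies, fell 3.69-fold, while Tapbp, tapasin, rose 2.25-fold.

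Neutrophil immunosuppression genes split, with 16 of 30 higher and 14 lower and each member past the threshold. The median log2 change was 0.89 (1.43 with equal total reads) and the mean -0.01, camera gave an adjusted p = 0.787, and fry placed the list lower. S100a8 fell from 187278 ± 5251 to 1469 ± 124 and Ifitm1 from 4535 ± 38.4 to 62.9 ± 7.89. Hmox1, heme oxygenase, rose from 1926 ± 7.08 to 22830.2 ± 889, and Cd274, which encodes PD-L1, rose from 865 ± 10.4 to 11999 ± 1677. Of 21 IL-4 and STAT6 target genes, 8 rose, 6 fell and 7 did not pass (camera adjusted p = 0.761). Tgm2, a transglutaminase, rose 11.7-fold from 985 ± 24.2 to 11958 ± 2045. Stat6 itself fell 2.34-fold and the IL-4 receptor gene Il4ra 4.14-fold.

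**Figure D2:**
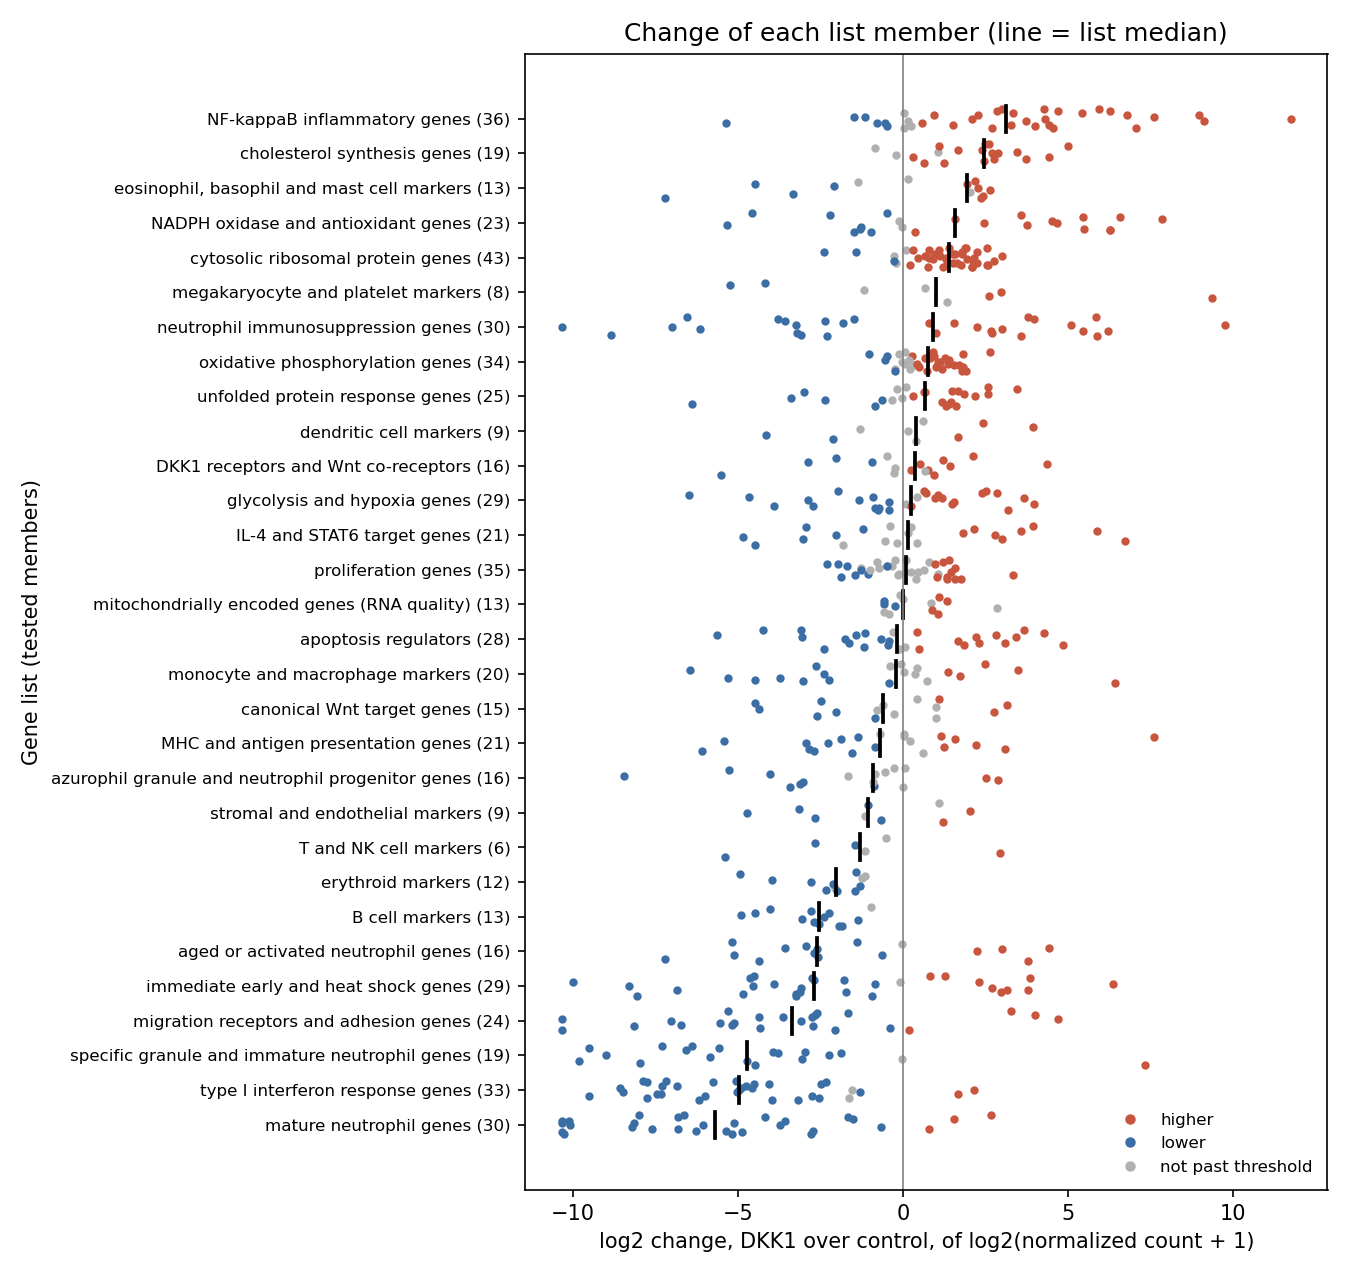
Log2 change (DKK1 over control, on the log2(normalized count + 1) scale) of each tested member of the 30 gene lists, with the list median as a black line and colours for members higher, lower or not past the limma threshold. List medians run from -5.72 for mature neutrophil genes to 3.14 for NF-kappaB inflammatory genes, and the medians of the apoptosis, monocyte and macrophage, and mitochondrially encoded lists lie at -0.19, -0.22 and -0.01, and are above 0 with libraries scaled to equal total reads.

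Cytosolic ribosomal protein genes rose together: 37 of 43 were higher, 3 lower and 3 not past the threshold (median log2 change 1.38, camera adjusted p = 1.47e-07; adjusted p = 0.269 with an estimated correlation). Rps2 rose 6.89-fold from 747 ± 57.1 to 5094 ± 275, and Rpl12 rose from 178 ± 8.18 to 1059 ± 18.1, while Rps9 fell 5.29-fold. Of 34 nuclear genes of oxidative phosphorylation, 22 rose, 4 fell and 8 did not pass (median 0.76, camera adjusted p = 0.00305; adjusted p = 0.434 with an estimated correlation). With equal total reads 29 rose, 1 fell and the median was 1.29. Cytochrome c1 (Cyc1) rose 3.85-fold from 69.4 ± 3.11 to 266 ± 9.55. Of 19 cholesterol synthesis genes, 16 rose and 3 did not pass, with 0 lower by limma at an unadjusted p under 0.05, by edgeR or by DESeq2 (median 2.45, camera adjusted p = 0.000255; adjusted p = 0.435 with an estimated correlation). Insig1, a sterol-responsive regulator, rose 13.4-fold from 57.7 ± 11.7 to 767 ± 37.7, and squalene synthase (Fdft1) rose from 41.1 ± 1.43 to 284 ± 21.7.

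Of 23 NADPH oxidase and antioxidant genes, 13 rose, 8 fell and 2 did not pass (median 1.58, camera adjusted p = 0.165). The cystine transporter gene Slc7a11 rose from 3730.02 ± 33.8 to 50943 ± 1152, and Gclc, which catalyses the first step of glutathione synthesis, rose 77.1-fold. The oxidase subunit gene Cyba rose from 2448 in control to 7313 in DKK1, while glutathione peroxidase 1 (Gpx1) fell 38.9-fold. Glycolysis and hypoxia genes split, with 14 of 29 higher, 13 lower and 2 not past the threshold (median 0.24, or 0.77 with equal total reads, mean -0.04, camera adjusted p = 0.761, lower by fry). The glucose transporter gene Slc2a3 fell 25.9-fold and triosephosphate isomerase (Tpi1) rose 9.21-fold. Of 25 unfolded protein response genes, 15 rose, 6 fell and 4 did not pass (camera adjusted p = 0.313). The chaperone gene Canx rose 11.1-fold and Chac1, a glutathione-degrading enzyme, fell 101-fold.

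Migration receptors and adhesion genes fell in 20 of 24 cases and rose in 4 (median log2 change -3.37, camera adjusted p = 5.06e-05; adjusted p = 0.0605 with an estimated correlation). Ccr1, a chemokine receptor, fell 110.1-fold from 16749 ± 263 to 159 ± 36.2. Of 16 aged or activated neutrophil genes, 11 fell, 4 rose and 1 did not pass (camera adjusted p = 0.0849). The tetraspanin gene Cd63 rose 7.98-fold and the integrin gene Itga4 fell 37.4-fold. Immediate early and heat shock genes gave 19 lower, 9 higher and 1 not past the threshold of 29 (median -2.70, camera adjusted p = 0.0755). The transcription factor gene Fos fell from 38067 ± 153 to 143 ± 38.4 and Fosb fell 1296-fold. The chaperone gene Hsp90aa1 rose 13.9-fold from 640.1 ± 33.4 to 8834 ± 249. Of 28 apoptosis regulators, 12 rose, 13 fell and 3 did not pass (camera adjusted p = 0.948). The pro-apoptotic gene Bax rose 19.1-fold, whereas Mcl1, a survival gene of neutrophils, fell 5.34-fold. Of 35 proliferation genes, 11 rose, 8 fell and 16 did not pass (camera adjusted p = 0.634), and with equal total reads 15 rose and 4 fell. Pcna rose 10.2-fold from 157 ± 3.85 to 1601 ± 63.1, and Mki67 rose 2.92-fold, while Gins2 fell 3.62-fold from 370.1 ± 16.9 to 101 ± 8.65.

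Markers of other cell types moved in differing directions. Of 20 monocyte and macrophage markers, 5 rose, 9 fell and 6 did not pass (camera adjusted p = 0.787). Cd68 rose 11.2-fold from 902 ± 43.7 to 10121 ± 286 and Ms4a7 rose from 1.76 ± 0.569 to 236 ± 17.8, while Ly6c2 fell 77.1-fold. Mpeg1 stood at 44162 ± 1003 in control and 42912 ± 4656 in DKK1. With equal total reads 8 of these markers were higher and 6 lower. B cell markers fell, 12 of 13 with 0 higher (median -2.54, -2.81 at the floor or -0.86 with a pseudocount of 10; camera adjusted p = 0.0156), and the adjusted p = 0.613 with an estimated correlation. Immunoglobulin mu (Ighm) fell from 1458 ± 70.8 to 49.3 ± 16.1. Erythroid markers fell in 9 of 12 cases, or in 5 with equal total reads, and 0 were higher under either scaling. Their median was -2.03, -2.0 at the floor or -1.23 with a pseudocount of 10. The camera adjusted p was 0.0219, and 0.435 with an estimated correlation. No B cell or erythroid marker was higher by limma at an unadjusted p under 0.05, by edgeR or by DESeq2; edgeR called 5 lower on each list. DKK1 library 2 stood apart on globin genes, with Hbb-bs at 582 against 297 and 117 in DKK1 libraries 1 and 3 and 682 ± 28.5 in control, and without that library 11 erythroid markers were lower. The B cell and erythroid calls were lost with a filter of 10 in 3 libraries (camera adjusted p = 0.0962 and 0.112, at the upper end of ranges from 0.00232 and 0.00371 over the alternatives of the fit).

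Camera called no list of the other marker sets. Of 6 T and NK cell markers, 1 rose, 3 fell and 2 did not pass (adjusted p = 0.472). Il7r rose 7.97-fold, Cd3d fell from 162 reads in control to 2 in DKK1, and Cd3g from 16 to 0. The list holds 16 markers, and those too low to test include the T cell genes Cd3e, Trac and Trbc2, each with 0 control reads. Of 13 eosinophil, basophil and mast cell markers, 6 rose, 4 fell and 3 did not pass (adjusted p = 0.886). The 4 that fell are eosinophil genes and the 6 that rose are genes of basophils or mast cells, a grouping made after the values were seen. The 3 that did not pass went against it. The eosinophil genes Epx (1 control read and 49 DKK1 reads) and Prg2 (24 and 187) stood higher, mostly from DKK1 library 3. Fcer1a, of basophils and mast cells, stood lower (8 and 2). Siglecf fell 240.3-fold from 292 ± 8.65 to 1.20 ± 1.13, and Gata2 rose 7.01-fold from 3.84 ± 2.38 to 26.4 ± 6.24. Of 9 dendritic cell markers, 3 rose and 2 fell (adjusted p = 0.787). Of 8 megakaryocyte and platelet markers, 3 rose and 2 fell (adjusted p = 0.634), and von Willebrand factor (Vwf) rose from 10.5 ± 2.02 to 7578 ± 717, while Gp1ba fell 22.97-fold and Clec1b 39.0-fold. Of 9 stromal and endothelial markers, 2 rose and 5 fell, or 3 with equal total reads (adjusted p = 0.472). The transcription factor gene Runx2 fell 25.1-fold and Col1a1, collagen, rose 2.26-fold. Of 13 mitochondrially encoded genes, read as a sign of RNA quality, 4 rose, 3 fell and 6 did not pass (median -0.01, mean 0.42, adjusted p = 0.761), and with equal total reads 7 rose. ND2 rose 2.53-fold. COX1 fell 1.49-fold, a call lost with equal total reads, quantile normalization or GC and length correction (limma adjusted p up to 0.782, within a range from 3.41e-11 over the alternatives). Mitochondrial ribosomal RNA took 0.127% ± 0.00208 of reads in control and 0.281% ± 0.0277 in DKK1.

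In 12018 of the 16265 tested genes (73.9%) the 3 DKK1 and 3 control values did not overlap, against 10% by chance. Correlations of log2 values across genes, which are not independent replicates, were 0.965 to 0.977 within groups and 0.698 to 0.710 between them. The limma fit on the normalized counts called 71.2% of tested genes, and edgeR on the recovered reads called 4982 higher and 4849 lower of 11870 genes it tested.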

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

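Scaling to equal total reads, the GC and length correction, and the edgeR and DESeq2 tests on recovered reads were chosen after the result was seen; the other alternatives were planned. Over all alternatives run, genes higher ranged from 4534 (log2 change of at least 1) to 7098 (equal total reads) and genes lower from 4742 (equal total reads) to 6033 (array weights), each within 1.5 times of 5709 and 5873. Leaving out 1 library gave 5409 to 5651 higher and 5483 to 5895 lower. DESeq2 called 5056 higher and 5440 lower. The median of all tested genes moved by 0.47 with equal total reads, 0.15 with quantile normalization and 0.15 with the GC and length correction. Opposite calls numbered 88, 61 and 4 under these 3 and 0 under each other alternative. Chil3 stayed lower and past the threshold in each of its alternatives, with adjusted p from 1.05e-07 to 0.0164 and log2 changes from -5.22 without DKK1 library 3 to -3.95 without DKK1 library 1.

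Camera called 10 lists, 2 of them with an estimated correlation, while fry called 26. Fry tests another question, so its count cannot be set against that of camera. Among lists that lost their call, the estimated correlation was negative, below the preset value, for specific granule (-0.0358) and migration (-0.0395) genes. A larger correlation between members thus does not account for the loss in these lists. The other lists that lost their call had estimates above the preset value, from 0.0584 to 0.493. Why calls were lost was not tested. Leaving out 1 library gave 10 to 11 called lists. Fry placed immunosuppression genes (median 0.894, fry adjusted p = 0.000511) and glycolysis and hypoxia genes (median 0.241, fry adjusted p = 0.00211) lower, against the sign of their medians; the means of both lists lie below 0, and the cause was not tested. Single lists changed their call 21 times to past and 10 times to not past the threshold. Without a filter, among other alternatives, the aged or activated and the immediate early lists passed (adjusted p = 0.0315 and 0.0227, ranges over the fit's alternatives 0.0315 to 0.137 and 0.0161 to 0.112). Calls of named genes were lost 6 times, for Lrp5, Gzma and COX1.

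No pairing by the shared sample numbers was detected: correlations of same-numbered deviations were -0.005, 0.007 and 0.017, and 3 of 6 libraries correlated best with their own number. Such correlations cannot exclude a shared animal or day. With the replicate block 5630 genes were higher and 5817 lower, and 10 lists were called. The simulated contrast, in which few genes changed, recovered 31.8% of changes of 0.5 on the log2 scale.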

Other observations

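The tests of lysosome, NRF2 and scavenger lists, of scaling, of monocyte or macrophage replacement, of column labels, of handling, of DKK1 library 2 and of control spread were chosen after the result was seen; the GC content and length test was added after the main result was seen but before its own, and the splits of the libraries were planned. Transcripts of lysosomes were high with DKK1: 28 of 39 tested genes rose and 7 fell (median log2 change 1.59). Prosaposin (Psap) rose from 21096 ± 205 to 102736 ± 2181, and the cathepsin gene Ctsb rose 21.1-fold from 2179 ± 51.9 to 46374 ± 2345 (SD, n = 3 each). The mannosidase gene Man2b1 fell 27.5-fold. Camera, adjusted over the 3 lists chosen after the data were seen, gave p = 3.43e-05, and adjusted p = 0.126 with an estimated correlation. Genes of the oxidative stress factor NRF2 and of iron handling rose in 20 of 27 cases and fell in 6 (median 3.77, adjusted p = 5.09e-05; adjusted p = 0.135 with an estimated correlation). Ferritin heavy chain (Fth1, which has pseudogene copies) rose 5.68-fold to 131532 ± 802, the transferrin receptor gene Tfrc rose 40.7-fold, and the iron exporter gene Slc40a1 fell 5.29-fold.

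Scavenger receptor and lipid handling genes rose in 17 of 22 cases and fell in 4 (median 2.39, adjusted p = 0.00149; adjusted p = 0.104 with an estimated correlation). Marco had 0 control reads and was at least 556-fold higher with DKK1, osteopontin (Spp1) rose 9.0-fold, and the cholesterol exporter gene Abcg1 fell 15.9-fold. The genes named here were chosen after their values were seen, so each list remains a hypothesis.

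As a cause of the fall of mature neutrophil transcripts, scaling between libraries is argued against, since the list's median remained -5.25 with equal total reads, and GC content or transcript length too, since 26 of the 27 genes called lower remained so with that trend removed. Replacement by monocytes or macrophages cannot be told apart from a change within the cells, because the 12 of their markers with a control mean under 100 moved both ways, 3 higher and 5 lower (4 and 3 with equal total reads). A difference in handling or time outside the animal cannot be told apart from DKK1, because the groups coincide with it: the median of immediate early and heat shock genes was -2.70, with Fos and Egr1 high in control. Columns that do not match their labels cannot be told apart from an effect of DKK1 either, since Cd101 and Ly6g reached at most 0.514% of their control means in each DKK1 library and 3 columns of the table match no sample. An effect of DKK1 on the cells, or survival of a few altered cells in culture, may also apply and stays untested.

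DKK1 library 2 stood apart from DKK1 libraries 1 and 3, with the amino acid response gene Trib3 at 716 against 64.1 and 90.6, Asns at 259.6 against 67.8 and 62.1, and the globin gene Hba-a2 at 555 against 228 and 98.8 (555 ± 55.6 in control). Its lower depth is argued against, since the variance between DKK1 libraries 1 and 2 over that of counting was 13.96 times as high for genes with 1000 or more reads as for genes with 20 to 200, and 1.17 times as high between libraries 1 and 3. A mixture with control cells is argued against too, since genes at least 64-fold lower with DKK1 lay at a median of -0.19 in library 2 relative to libraries 1 and 3. These genes were chosen on all 3 DKK1 libraries, library 2 included. Genes raised in library 2 could thus drop out, and a small mixture is not excluded. No biological explanation was tested, and a difference in culture state stays possible.

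The control libraries differed little, with a median coefficient of variation of 4.60% against 8.86% in DKK1 over 4753 genes. Their variance was 2.21 to 2.26 times that of counting and changed little with depth, by a factor of 1.26 at most. Whether the 3 controls came from a shared pool of RNA cannot be told apart from cultures that varied little, because such a comparison sets single libraries against technical noise.

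The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5709 genes higher and 5873 lower and the highest other split 0 of each by limma. Every other split mixes control and DKK1 libraries on each side, so the group difference enters its spread and keeps its gene calls low. At an unadjusted p under 0.05 the other splits gave 50 to 84 genes higher and 53 to 78 lower; edgeR and DESeq2 were not run on them. For lists, the real split called 10 and the highest other split 9. The real split alone gave each result as large, 1 of 10 in each case. Because the other splits also keep part of the group difference, neither their gene counts nor their list counts measure chance.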
